A study of Wollemia nobilis with 9 samples.

How the data were processed

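RNA from leaf, ovule and pollen of Wollemia nobilis (the Wollemi pine, a conifer of the family Araucariaceae) was sequenced in 9 libraries, 3 per tissue. Per the labels' protocols, RNA was taken up in PureLink Plant RNA Reagent and 100 ng of total RNA per library went into the Kapa mRNA Hyper prep kit, which selects messenger RNA. Per the submitters' processing notes, reads were aligned with STAR; its version and the name of the genome build are not given in the sources used here. The labels do not say whether replicates came from separate trees, from separate organs of 1 tree or from 1 pool of tissue.

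Per the file headers, the authors made the deposited count tables with featureCounts 2.0.1, counting read pairs as fragments over the whole span of each gene, introns included, with no strand option. Per the file headers, no option to count multi-mapping fragments or fragments over several genes was set, so by the program's defaults such fragments were left out. Each table holds whole-number counts for the same 37484 gene models of annotation Wono_1.6, which was deposited with descriptions, positions and exons. The deposited values were not normalised. Gene names used here are those descriptions, and positions are the contig with the first and last base of the gene in that annotation. For 1 gene, which is not named in the text, the start in the count tables differed from that in the annotation.

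Counting without strand means that genes with overlapping spans lose the fragments in the shared part, or cannot be told apart there. In the annotation, 7823 genes (20.9%) overlap another gene, and 47.2% of them had no count in any library, against 11.9% of the other genes. Of the 177 genes chosen by the rule below, 29 overlap another gene, and their values are uncertain. Fragments from near-identical copies of a gene were not counted where they aligned equally well to several places, so that levels in multigene families are lower limits; no genome sequence was at hand to find such copies.

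Counts were analysed in R 4.3.3. Genes with enough counts by the default filter of edgeR 4.0.16 were kept (22780 of 37484; 7211 had no count in any library), and libraries were scaled by trimmed mean of M values (TMM). All 3 tissues entered 1 quasi-likelihood fit with robust dispersion and no covariate, so that they share the estimate of spread. Each pair of tissues was tested by a contrast, and an F test asked whether a gene differed among the 3 tissues. A gene was called in a comparison when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 fold change at least 1 in size. A gene was called highest in a tissue when it was called higher there than in both others. A gene was detected in a tissue when it had at least 1 CPM (counts scaled to a common library size), taken from the library totals, in all 3 libraries; all other CPM values use library sizes adjusted by TMM factors. The p-values measure only the spread between these libraries.

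Total counts ran from 25602114 to 32122737 per library. Where a tissue had no count of a gene, its level is set at a floor of 3 counts over the 3 libraries (0.0353 CPM in leaf, 0.0248 in ovule and 0.0507 in pollen), and the fold change is given as a lower bound. Where it had 1 to 3 counts, the ratio of mean CPM is given with its exact 95% Poisson counting interval. Fragments from PCR-amplified libraries without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Values are given as mean CPM ± SD (n = 3), and errors of log2 fold changes are standard errors (SE).

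Before the data were examined, 26 gene lists were fixed as patterns of symbols and words to be matched in the deposited descriptions. The patterns matched 1523 entries. Those whose description belonged to another protein were left out after the matches were seen and before any list was tested, which left 1329. Lists with at least 5 tested members (23) were tested in the 3 comparisons with camera of limma 3.58.1, a test of whether a list's members rank higher or lower than other genes. Its correlation between genes was preset at 0.01, and its 69 p-values were adjusted together. The same test with an estimated correlation and the rotation test fry were run as alternatives. Ranges of a list's adjusted p are over the alternatives that keep the preset correlation, and so leave out these tests. List medians were also computed with genes at 0 counts in a tissue placed at their bound. Genes at 0 counts in both tissues were left out of these medians, as were genes at 0 counts against at most 3. The plain medians hold genes at 0 counts in both tissues at a log2 fold change of 0. The medians with bounds can thus rest on fewer genes, and some are larger in size than the plain ones. For the stomatal lineage list in pollen against leaf, the median went from 0 to -3.56.

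The genes named in the text were chosen by a rule fixed before the data were examined. It takes per comparison the 6 described genes with the highest and the 6 with the lowest fitted log2 fold change, among called genes of at least 10 CPM in the higher tissue whose library values do not overlap. It adds the called member of each list with the smallest adjusted p in each direction, the 5 described genes with the highest mean CPM of each tissue, and the called members of the MADS-box and the DNA methylation and small RNA lists. A gene named outside the rule is said to be so.

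The procedure was tested on simulated counts with the means and library sizes of these libraries, in which 100 genes were changed per fold size. The changed genes were drawn only from those above a minimum mean count, so recovery of genes with few counts was not tested. In pollen against leaf it recovered 81% of genes changed 3-fold and 98% of those changed 8-fold among 21938 genes; in pollen against ovule it recovered 82% and 98%. Among unchanged genes it made 8 false calls in pollen against leaf, 1 in ovule against leaf and 6 in pollen against ovule. The simulated tissues differed only in the changed genes, whereas 22021 of 22780 tested genes differed among the real tissues. The simulation therefore did not test scaling where most genes change. Its recovery and false calls hold for the simulated counts and do not give error rates for these comparisons.

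The alternatives were scaling by relative log expression (RLE) or by library totals, other filters on low counts, a block for replicate number, each library left out in turn, DESeq2 1.42.0, limma with voom weights, a fit of only the 2 tissues compared, other fold thresholds and other detection limits. Alternatives added after the data were seen were the lists as first matched and the counts without ovule library 3 and pollen library 3, which stood apart from their replicates. Other splits of the libraries were drawn as described in the closing section. Transposons outside gene models, splice forms and allele-specific expression were not analysed here.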

Results

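The transcriptomes of leaf, ovule and pollen of the Wollemi pine were measured by RNA sequencing, with 3 libraries per tissue. Counts assigned to genes ran from 26384085 to 28325689 per leaf library, from 28723638 to 32122737 per ovule library and from 25602114 to 28517315 per pollen library. Of 37484 annotated genes, 22780 had enough counts to be tested, and 11562 of these (50.8%) carried a description. Levels are mean CPM, counts scaled to a common library size, ± SD over the 3 libraries of a tissue (n = 3). The p-values measure only the spread between these libraries, since the labels do not say whether replicates were separate plants, and intervals and lower bounds cover counting error only. Positions are those of annotation Wono_1.6.

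The 3 tissues had separate transcriptomes. The libraries of a tissue correlated at r = 0.98 to 0.995 across genes and those of different tissues at 0.488 to 0.587; genes are not independent replicates. In edgeR's F test 22021 of the 22780 genes differed among the tissues at an adjusted p under 0.05. Leaf had 5163 genes called higher than in both other tissues, ovule 4399 and pollen 3711. Independent lists of calls would overlap in 2763, 2745 and 1449 genes, and simulated tissues without differences gave 0. Because each pair of comparisons shares the libraries of 1 tissue, part of the excess over these values may come from the shared libraries. The genes highest in pollen made up 61.2 ± 0.37% of the pollen counts, those highest in leaf 44.1 ± 0.31% of the leaf counts and those highest in ovule 26.4 ± 1.1% of the ovule counts. At 1 CPM or more in all 3 libraries, 16730 genes were detected in leaf, 16954 in ovule and 13309 in pollen, and 11295 were detected in every tissue.

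**Figure D1:**
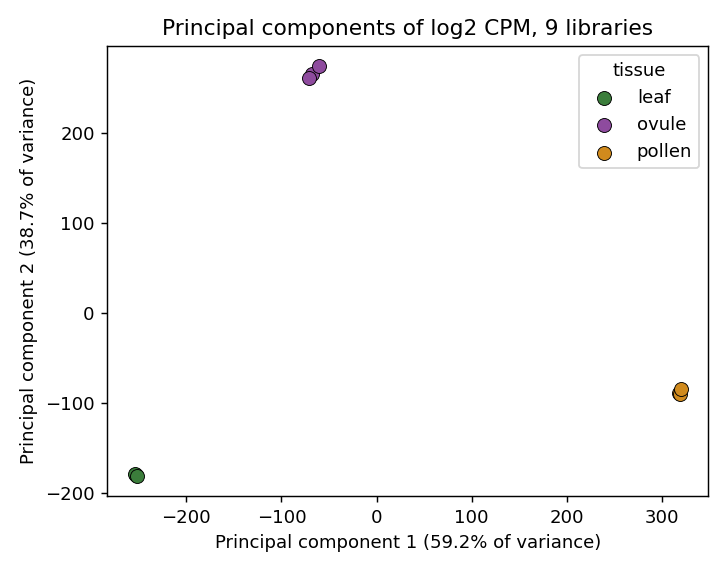
Principal components of log2 CPM of the tested genes, 1 point per library (9 libraries, 3 per tissue); the axes are the first component (59.2% of the variance) and the second (38.7%). The libraries of each tissue lie close together, with pollen at 318.5 to 320.3 on the first axis and ovule at 261.4 to 274.4 on the second.

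The described genes with the highest CPM differed between the tissues. CPM is not corrected for gene length, so this order ranks fragments rather than transcripts. Leaf was led by Wono307720, a chloroplast fructose-bisphosphate aldolase of carbon fixation (6635 ± 202 CPM), and by the rubisco activases Wono378430 (5484 ± 221 CPM) and Wono035550 (4728 CPM), which keep the carbon-fixing enzyme active. The metallothionein Wono149680 reached 5673 CPM in leaf, an uncertain value because its span overlaps another gene. Ovule was led by the translation factor EF1-alpha Wono426230 (4415 CPM, against 4510 in leaf), the chaperones Wono191450 (2436 CPM) and Wono249560 (1714 CPM), and the chromatin protein HMGB1 Wono447040 (2190 ± 223 CPM, against 90.5 in leaf and 41.5 in pollen). Pollen was led by Wono297510, a pathogenesis-related protein of the BetVI family (45530 ± 4316 CPM), and the pollen allergen Wono236800 (14110 ± 1291 CPM). They were followed by the late embryogenesis type protein Wono059750 (11640 ± 2734 CPM), the UDP-arabinopyranose mutase Wono190170 (11460 ± 765 CPM), which makes a sugar donor for cell walls, and the alcohol dehydrogenase Wono065960 (8935 ± 786 CPM). Members of multigene families such as BetVI, chlorophyll-binding proteins and oleosins are uncertain where near-identical copies share reads.

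The fold changes are relative to the scaling. With TMM factors the median log2 change of all tested genes was -0.37 in pollen against leaf, 0.03 in ovule against leaf and -0.48 in pollen against ovule. With library totals it was -0.89, 0.38 and -1.36, and with RLE factors -0.30, -0.02 and -0.32.

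In pollen compared with leaf, 30 of 33 photosystem and 9 of 10 Calvin cycle genes were lower, and 16 of 23 genes of the seed storage, oil body and late embryogenesis list were higher and 5 lower. Camera called these lists, but with an estimated correlation none passed (adjusted p = 0.346, 0.246 and 0.284). Photosystem transcripts summed to 27060 ± 1210 CPM in leaf and 202.3 ± 29 in pollen, and those of the Calvin cycle to 19560 ± 573 and 19.13 ± 1.7 CPM. The seed storage, oil body and late embryogenesis list summed to 226.4 ± 7.15 CPM in leaf and 4340 ± 527 in pollen, a sum that does not hold the late embryogenesis type protein Wono059750 (11640 ± 2734 CPM), whose description matched no pattern of the list. Of the genes with the highest fold, the BetVI protein Wono297510 was 2010000 times higher in pollen (counting interval 535000 to 16000000, from 2 leaf counts), and the cytokinin dehydrogenase Wono260520, which degrades the hormone cytokinin, reached 7359 ± 956 CPM and was at least 208000-fold higher. In all, edgeR called 15323 of 22780 tested genes (67.3%), 6110 higher and 9213 lower in pollen (39.9% of the called higher). Counts of list members are to be read against these numbers for all genes. With library totals 4729 were higher and 10683 lower (30.7% higher). The libraries of 19419 genes (85.2%) did not overlap, against 10% by chance.

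The genes with the highest fold in pollen also included the pollen allergen Wono236800, 1180000 times higher (interval 215000 to 47300000, from 1 leaf count). The aquaporin Wono267480, a water channel (contig_31227, bases 59351 to 65448, 4 exons), reached 4468 ± 277 CPM and was at least 126000-fold higher. The endoglucanase Wono206070, which acts on cell wall glucan (contig_23860, bases 4345715 to 4348314, 8 exons), was at least 79700-fold higher, and the HOTHEAD-like protein Wono368710 at least 53900-fold higher. The BetVI gene lay on contig_5238 at bases 5964169 to 6016817 (4 exons), the allergen gene on contig_26256 at 684994 to 687947 (9 exons) and the cytokinin dehydrogenase on contig_28040 at 672228 to 676186 (5 exons). On the leaf side, the carbonic anhydrase Wono263930 (contig_2965, bases 123085 to 132420, 9 exons), which interconverts carbon dioxide and bicarbonate, reached 2109 ± 71.4 CPM and was at least 41600-fold lower in pollen. The chlorophyll a-b binding protein Wono101740 was at least 32200-fold lower, the metal-binding HIPP39-like protein Wono411400 at least 31300-fold, and the receptor kinase Wono325240 at least 18500-fold. The asparagine synthetase Wono343620 was at least 17200-fold lower, and Wono022180, subunit B of the Calvin cycle's glyceraldehyde-3-phosphate dehydrogenase, at least 17100-fold.

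The photosynthesis lists fell in pollen. Of 33 tested photosystem and light-harvesting genes, 30 were lower and 1 higher (median log2 change -11.70; camera adjusted p = 7.45e-08, and adjusted p = 0.346 with an estimated correlation). The antenna gene Wono279610 (contig_3696, bases 3054300 to 3058936) went from 2519 to 0.203 CPM (log2 change -13.57). The higher member, psbA-like Wono470880, overlaps another gene and is uncertain (0.129 CPM in leaf, 1.05 in pollen). Of 10 Calvin cycle genes, 9 were lower and 0 higher (camera adjusted p = 0.000167, and adjusted p = 0.246 with an estimated correlation), among them the phosphoribulokinase Wono165550 (contig_21500, bases 6334889 to 6338893), which was 35300 times lower (interval 12400 to 176000). Of 11 chlorophyll synthesis genes, 9 were lower and 0 higher (median -4.39; camera adjusted p = 0.00359, and adjusted p = 0.246 with an estimated correlation), among them magnesium chelatase subunit ChlI Wono245540 (log2 change -8.71). The counts of higher and lower members given for all lists in this comparison were the same adjusted over the list alone.

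Of 23 tested seed storage, oil body and late embryogenesis genes, 16 were higher and 5 lower (median log2 change 7.61, or 6.14 with genes at 0 counts placed at their bound; camera adjusted p = 0.0013, and adjusted p = 0.284 with an estimated correlation). The oleosin Wono328570, a coat protein of oil bodies (contig_8320, bases 1662975 to 1663415, 1 exon), was 265 times higher at 1488 ± 131 CPM, and the late embryogenesis protein Wono413420 was lower (log2 change -6.88). The actin cytoskeleton list had 16 higher and 10 lower of 46; its median was 0.68 and its mean -0.17, and camera placed it higher at an adjusted p of 0.0263 (adjusted p = 0.346 with an estimated correlation). With library totals its median was 0.15 and its camera adjusted p 0.0836, in a range of 0.0185 to 0.0836 with the preset correlation. The actin-bundling proteins fimbrin Wono073410 (log2 change 3.43) and villin Wono193830 (-7.41) moved in opposite directions. Of 129 ribosomal protein genes 36 were higher and 8 lower (median 0.50, but -0.03 with library totals; camera adjusted p = 0.000152, and adjusted p = 0.698 with an estimated correlation). Over all 22780 tested genes 6110 were higher and 9213 lower. The share of higher members was thus near that of all genes, and the list differed by its few lower members. Of 26 cell cycle genes 12 were higher and 3 lower (median 1.01, or 1.1 with bounds; camera adjusted p = 0.0495, and adjusted p = 0.646 with an estimated correlation), including the mitotic cyclin Wono276810 (log2 change 1.51, or 0.98 with library totals). The cell cycle call ended with RLE scaling (camera adjusted p = 0.0513) and without pollen library 3 (0.0557), in a range of 0.028 to 0.0557 with the preset correlation.

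Defence, terpenoid and organ boundary lists fell in pollen. Of 177 immune receptor and defence genes 140 were lower and 22 higher (median log2 change -7.23, or -5.32 with bounds; camera adjusted p = 3.48e-06, and adjusted p = 0.228 with an estimated correlation), while their summed level was 2951 CPM in leaf and 47100 in pollen, of which Wono297510 made up 45530. Among them, the resistance-type protein Wono196470 was lower (log2 change -6.81) and the chitinase-like Wono117870 higher (3.05). Of 29 terpenoid genes 20 were lower and 0 higher (median -7.43, or -5.88 with bounds; camera adjusted p = 0.0013, and adjusted p = 0.27 with an estimated correlation), and their sum was 542.8 ± 12.4 CPM in leaf and 46.03 ± 9.62 in pollen. The geranylgeranyl diphosphate synthase Wono429530, an enzyme of isoprenoid precursor synthesis, had a log2 change of -5.21. Of 23 ovule and organ boundary regulators 14 were lower and 0 higher (median -4.93, or -4.34 with bounds; camera adjusted p = 0.0113, and adjusted p = 0.346 with an estimated correlation); the BEL1-like gene Wono076920 went from 1004 to 0.135 CPM, an uncertain value since its span overlaps another gene.

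Other lists did not pass camera in pollen against leaf. The signalling genes of pollen tubes had 4 higher and 5 lower of 13 (adjusted p = 0.875); the exchange factor RopGEF9 Wono187510 (contig_22877, bases 1191083 to 1196556, 10 exons), which activates the ROP switches of tip growth, was 2010 times higher at 380.8 ± 48.2 CPM. Pectin-modifying enzymes had 15 higher and 18 lower of 44 (0.395), and the pectinesterase Wono178950, which demethylates wall pectin, rose to 814.4 CPM (log2 change 3.98). The flavonoid list had 10 higher and 17 lower of 40 (0.853); chalcone synthase Wono365340 (scaffold_11582, bases 1698384 to 1699643, 2 exons), the entry enzyme of flavonoid synthesis, rose to 1664 ± 222 CPM (log2 change 12.76). Phenylpropanoid and lignin genes had 18 higher and 31 lower of 62 (0.817), with the coumarate ligase-like gene Wono252640 3880 times higher (interval 1070 to 31800). Sugar transport and starch had 19 higher and 37 lower of 68 (0.171), while alpha-amylase Wono387820, which breaks down starch, rose to 2699 ± 24.7 CPM (3.04). Light signalling had 5 higher and 12 lower of 26 (0.221), and the CONSTANS-like gene Wono012480 was 11900 times lower (interval 2090 to 460000). Heat shock proteins had 7 higher and 25 lower of 54 (0.435), cuticle and wax 5 and 10 of 23 (0.986), xylem 4 and 2 of 7 (0.534), sporopollenin 3 and 2 of 11 (0.729) and stomatal lineage 0 and 1 of 5 (0.986). Camera's direction was up where the mean was negative for pectin enzymes (-0.06), pollen tube signalling (-0.35) and xylem (-1.66).

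In the MADS-box list, 2 of 26 genes were higher and 15 lower in pollen than in leaf (camera adjusted p = 0.123). The SOC1-like gene Wono318990 was 4990 times lower (interval 875 to 193000), and Dal1 Wono474290 was 27.2 times higher in pollen (interval 9.30 to 132) at 0.961 CPM. DNA methylation and small RNA genes had 12 higher and 13 lower of 33 (camera adjusted p = 0.85; median -0.54, mean 0.28). The methyltransferase DRM2-like gene Wono424990, of a family that establishes DNA methylation, was 1560 times higher (interval 286 to 62900), and the Dicer-like gene Wono051800 rose from 8.34 to 57.7 CPM. SGS3 Wono344850, a partner in the making of small RNA precursors, was at least 434-fold lower. The RNA-dependent RNA polymerases Wono181100 (log2 change 7.55) and Wono429280 (-7.58) moved in opposite directions. The demethylase DEMETER Wono097160 rose from 2.87 to 59.5 CPM, an uncertain value because its span overlaps another gene.

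**Figure D2:**
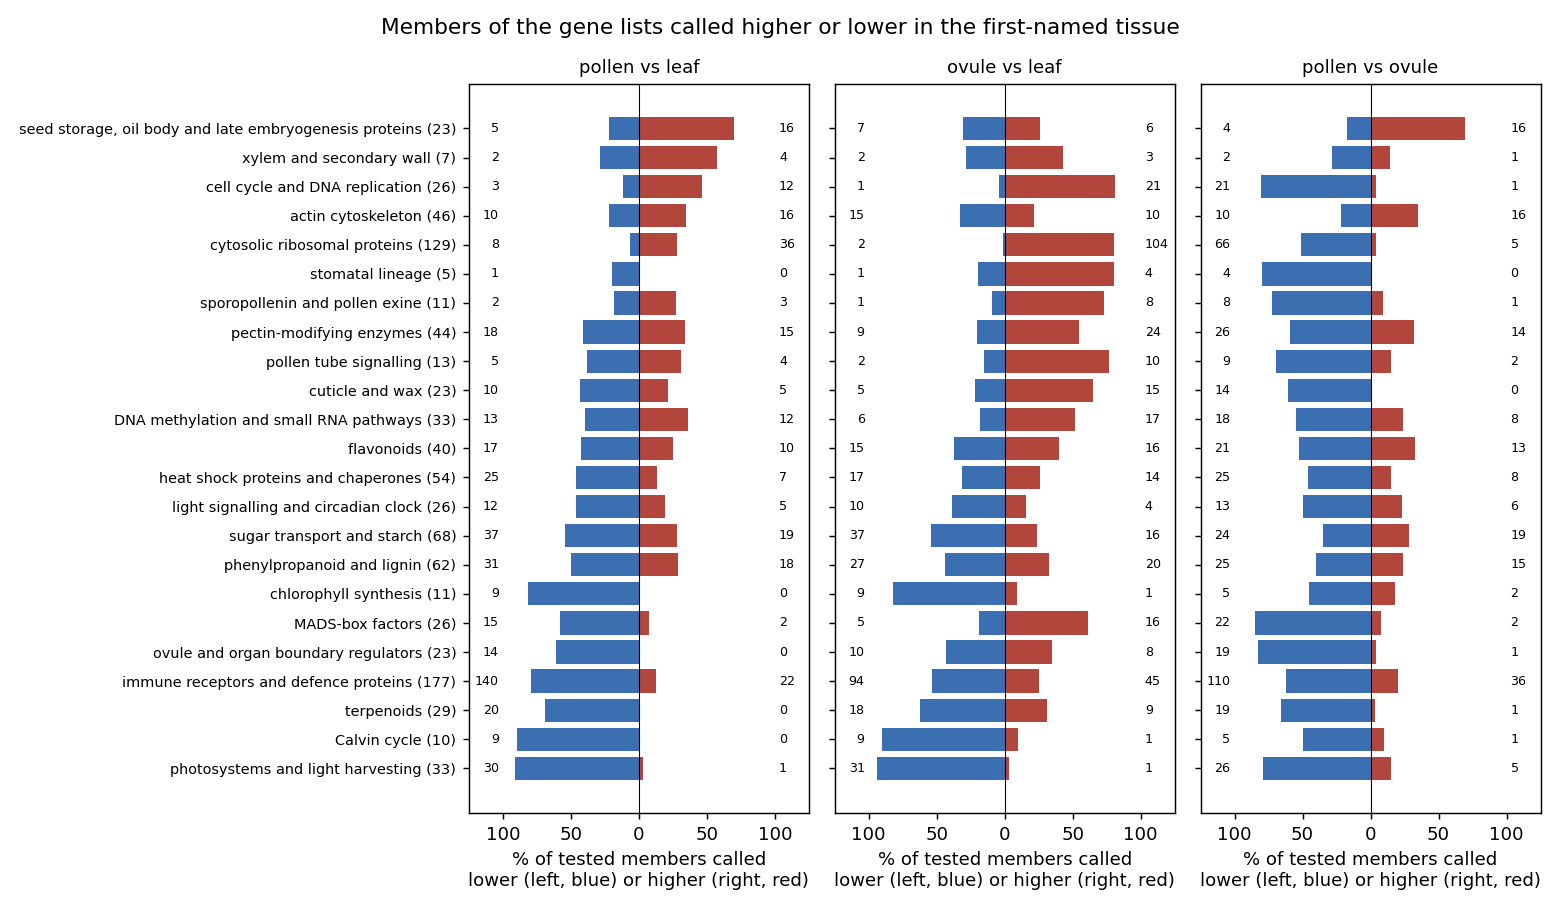
Percent of the tested members of each gene list called lower or higher, in 3 panels for the 3 comparisons, with the counts of members beside the bars. Photosystem genes were lower in pollen than in leaf in 30 of 33 cases, and ribosomal protein genes were higher in ovule than in leaf in 104 of 129. Over all tested genes, 67.3% were called in pollen against leaf, 60.2% in ovule against leaf and 63.7% in pollen against ovule.

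In ovule compared with leaf, 21 of 26 cell cycle, 104 of 129 ribosomal protein and 16 of 26 MADS-box genes were higher (1, 2 and 5 lower), and 31 of 33 photosystem genes were lower. Camera called these lists, but with an estimated correlation none passed (adjusted p = 0.346, 0.346, 0.254 and 0.246). Cell cycle transcripts summed to 195.2 ± 3.1 CPM in leaf and 3321 ± 662 in ovule, ribosomal proteins to 13540 ± 622 and 38730 ± 2940, and MADS-box factors to 285.3 ± 7.43 and 1831 ± 81.6. The cell cycle sums were 3580, 3814 and 2568 CPM in ovule libraries 1, 2 and 3. Photosystem transcripts were at 456.4 ± 98.7 CPM in ovule. In all, edgeR called 13704 of 22780 tested genes (60.2%), 6873 higher and 6831 lower in ovule (50.2% of the called higher). The balance turned with the scaling, at 8210 higher and 5902 lower with library totals (58.2% higher) and 6508 higher and 7116 lower with RLE factors (47.8% higher). The libraries of 19289 genes (84.7%) did not overlap, against 10% by chance.

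The genes with the highest fold in ovule had no leaf count. They were endoglucanase Wono441550 (scaffold_26913, bases 5165737 to 5168679, 8 exons), at 1550 ± 156 CPM and at least 43900-fold higher, and AGAMOUS Wono428320 (scaffold_24681, bases 2323808 to 2382380, 9 exons), a MADS-box factor of reproductive organ identity, at 948.8 ± 84 CPM and at least 26900-fold higher. The lipid transfer proteins Wono120690 (635.5 ± 142 CPM) and Wono120700 (267.5 ± 57.3 CPM), on the same contig, were at least 18000-fold and 7570-fold higher. The thaumatin-like gene Wono036850 (383.7 ± 52.3 CPM) was at least 10900-fold higher, and the MADS-box gene GGM13 Wono119760 (contig_18672, bases 2668963 to 2734282, 9 exons; 215.8 ± 27.6 CPM) at least 6110-fold. On the leaf side, HIPP39-like Wono411400 was at least 64000-fold lower in ovule, the receptor kinase Wono325240 at least 37800-fold, asparagine synthetase Wono343620 at least 35300-fold, and GAPB Wono022180 at least 35100-fold. The alkyl transferase Wono409190 was at least 17200-fold lower. Galactinol synthase Wono193010 overlaps another gene, so that its ratio of 197000 (interval 57100 to 1700000) is uncertain.

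Ribosomal protein, cell cycle, pollen tube signalling and pectin lists rose in ovule. Of 129 ribosomal protein genes 104 were higher and 2 lower (median log2 change 1.5; camera adjusted p = 3.15e-16, and adjusted p = 0.346 with an estimated correlation), among them L23 Wono296650 (63.1 to 270.6 CPM). Of 26 cell cycle genes 21 were higher and 1 lower (median 6.41, or 6.09 with bounds; camera adjusted p = 2e-06, and adjusted p = 0.346 with an estimated correlation). The replication licensing factor MCM6 Wono056940 (contig_14204, bases 397663 to 408065, 18 exons) was 530 times higher at 388.9 ± 86.6 CPM, and cyclin Wono232630 had a log2 change of -1.98. Of 13 pollen tube signalling genes 10 were higher and 2 lower (median 2.67; camera adjusted p = 0.00762, and adjusted p = 0.246 with an estimated correlation), among them the ROP-type switch RAC2 Wono102370 (1.84 to 41.8 CPM). Of 44 pectin-modifying enzymes 24 were higher and 9 lower (median 1.78, or 2.09 with bounds; camera adjusted p = 0.0197, and adjusted p = 0.346 with an estimated correlation), among them pectinesterase Wono216910 (1.48 to 254.1 CPM). With library totals the pectin call ended (camera adjusted p = 0.0725, in a range of 0.0116 to 0.0725 with the preset correlation).

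Most tested MADS-box genes were higher in ovule than in leaf. Of 26 tested, 16 were higher and 5 lower (median log2 change 2.09; camera adjusted p = 0.0134, and adjusted p = 0.254 with an estimated correlation). The gene Dal1 Wono474290 (scaffold_8161, bases 4834862 to 5087913, 8 exons) was 7450 times higher in ovule (interval 2550 to 36200). The MADS16-like gene Wono110200 (contig_17919, bases 5725925 to 5727942, 7 exons) reached 107.6 ± 27.4 CPM and was at least 3040-fold higher. Also without a leaf count were Wono110100 (at least 441-fold) and the TCAP3-like Wono110080 (at least 70.9-fold), while DAL21 Wono432790 rose from 0.527 to 16.5 CPM. Lower in ovule were AGL15 Wono085080 (46.9 to 9.08 CPM), SVP Wono338690 (78.3 to 5.84 CPM) and MADS23 Wono397490, at least 1020-fold.

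**Figure D3:**
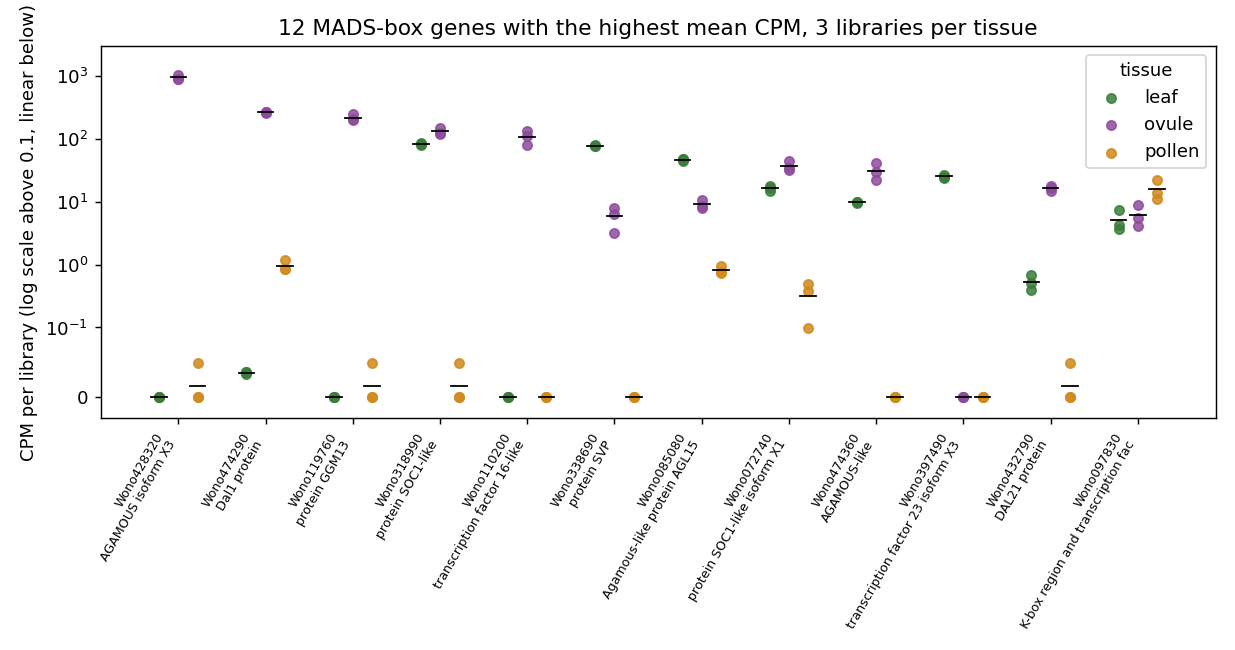
CPM of the 12 MADS-box genes with the highest mean, 1 point per library (3 leaf, 3 ovule, 3 pollen), with a bar at the mean; the axis is logarithmic above 0.1 CPM and linear below. AGAMOUS stood at 948.8 CPM in ovule, at 0 in leaf and at 0.0164 in pollen.

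Reproductive-wall, lipid and photosynthesis lists also changed in ovule. Of 11 sporopollenin genes, whose products make the pollen coat polymer, 8 were higher and 1 lower (median log2 change 7.59, or 7.13 with bounds; camera adjusted p = 0.0166, and adjusted p = 0.27 with an estimated correlation); the reductase FAR2 Wono466790 (scaffold_6192, bases 11954453 to 11957721) was at least 420-fold higher at 14.84 ± 2.2 CPM. With library totals the camera adjusted p was 0.05, in a range of 0.00526 to 0.05 with the preset correlation. Of 23 cuticle and wax genes 15 were higher and 5 lower (median 2.77; camera adjusted p = 0.0305, and adjusted p = 0.246 with an estimated correlation), among them CER3 Wono313530 (1.5 to 47.3 CPM), but with library totals the p was 0.0891, in a range of 0.0222 to 0.0891 with the preset correlation. Photosystem genes were lower in 31 of 33 cases and higher in 1 (median -5.92; camera adjusted p = 4.62e-10, and adjusted p = 0.246 with an estimated correlation). The antenna gene Wono410370 went from 1343 to 0.22 CPM. Calvin cycle genes were lower in 9 of 10 and higher in 1 (median -10.09; camera adjusted p = 0.00022, and adjusted p = 0.246 with an estimated correlation), with GAPA Wono304640 at 2057 CPM in leaf and 0.218 in ovule. Of 11 chlorophyll synthesis genes 9 were lower and 1 higher (median -2.67; camera adjusted p = 0.00151, and adjusted p = 0.246 with an estimated correlation).

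Of 177 immune genes 94 were lower and 45 higher in ovule than in leaf (median log2 change -1.54, or -1.47 with bounds; camera adjusted p = 0.0148, and adjusted p = 0.246 with an estimated correlation). Of 68 sugar transport and starch genes 37 were lower and 16 higher (median -1.11, or -1.13 with bounds; camera adjusted p = 0.0195, and adjusted p = 0.27 with an estimated correlation); with the list as first matched the p was 0.0507, in a range of 0.0157 to 0.0507 with the preset correlation. Of 29 terpenoid genes 18 were lower and 9 higher (median -1.79; camera adjusted p = 0.0316, and adjusted p = 0.46 with an estimated correlation). Their sums were 176.1, 158.6 and 1272 CPM in ovule libraries 1, 2 and 3, and the call ended without ovule library 3 (camera adjusted p = 0.0505) and without ovule library 3 and pollen library 3 together (0.0552), in a range of 0.0133 to 0.0552 with the preset correlation. The ent-kaurene synthase Wono437020, an enzyme of gibberellin synthesis, went from 63.4 to 0.982 CPM. The levopimaradiene synthase Wono221950, of resin acid synthesis, had a log2 change of 4.39, an uncertain value because its span overlaps another gene.

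Other lists did not pass camera in ovule against leaf. DNA methylation and small RNA genes had 17 higher and 6 lower of 33 (median log2 change 1.12; adjusted p = 0.0556). The p was 0.0497 with a replicate block, 0.0499 without leaf library 1, 0.0375 without ovule library 2, 0.0452 without ovule library 3 and 0.0483 without ovule library 3 and pollen library 3 together, in a range of 0.0375 to 0.0891 with the preset correlation; it was 0.346 with an estimated correlation. AGO10 Wono021840 (contig_11860, bases 737216 to 748093, 23 exons), an Argonaute of shoot and organ development, rose to 164.8 ± 27.6 CPM (log2 change 6.94). The methyltransferase Wono082920 rose from 19.6 to 151.6 CPM, the chromatin remodeller DDM1 Wono111960 was at least 491-fold higher, and Dicer-like Wono409900 was lower (log2 change -3.87). Ovule and organ boundary regulators had 8 higher and 10 lower of 23 (adjusted p = 0.562; median -0.63, mean 0.72). The LEAFY homolog Wono337930 (contig_891, bases 3122202 to 3402189, 8 exons), a factor of reproductive identity, was 1200 times higher at 57.7 ± 16 CPM, and the BEL1-like gene Wono302050 had a log2 change of -11.83. Flavonoid genes had 16 higher and 15 lower of 40 (0.986), with leucoanthocyanidin dioxygenases in both directions (Wono333860 5.76, Wono208500 -9.32). Actin had 10 higher and 15 lower of 46 (0.986, direction up with a mean of -0.39), phenylpropanoid 20 and 27 of 62 (0.392), heat shock 14 and 17 of 54 (0.986; median -0.08, mean 0.08), light signalling 4 and 10 of 26 (0.435), xylem 3 and 2 of 7 (0.986) and stomatal lineage 4 and 1 of 5 (0.174; 0.0436 as first matched, in a range of 0.0436 to 0.3 with the preset correlation, and 0.346 with an estimated correlation). Seed storage, oil body and late embryogenesis genes had 6 higher and 7 lower of 23 (0.991), and 5 higher adjusted over the list alone; all other counts of this comparison were the same adjusted over the list alone.

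In pollen compared with ovule, 16 of 23 genes of the seed storage, oil body and late embryogenesis list were higher and 4 lower, and 22 of 26 MADS-box, 21 of 26 cell cycle and 66 of 129 ribosomal protein genes were lower (2, 1 and 5 higher). Camera called these lists, but with an estimated correlation none passed (adjusted p = 0.246, 0.246, 0.346 and 0.646). The seed storage, oil body and late embryogenesis list summed to 4340 ± 527 CPM in pollen and 167.1 ± 1.6 in ovule, and MADS-box factors to 19.66 ± 5.68 and 1831 ± 81.6. Cell cycle transcripts summed to 353.4 ± 40.1 CPM in pollen and 3321 ± 662 in ovule, and ribosomal protein transcripts to 20820 ± 1600 and 38730 ± 2940. Dal1 Wono474290 was 274 times lower in pollen, MCM6 Wono056940 108 times lower and RopGEF9 Wono187510 198 times higher. In all, edgeR called 14501 of 22780 tested genes (63.7%), 5404 higher and 9097 lower in pollen (37.3% of the called higher). With library totals 3430 were higher and 12147 lower (22% higher). The libraries of 18394 genes (80.7%) did not overlap, against 10% by chance.

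Among the genes with the highest fold in pollen, HOTHEAD Wono368720 (scaffold_12568, bases 656624 to 669356, 6 exons) was at least 11000-fold higher at 273 ± 23.7 CPM, the protease RD19D Wono463260 (227 ± 48.8 CPM) at least 9160-fold, and the kinase OXI1 Wono031590 (144.5 ± 47.4 CPM) at least 5830-fold. The transporter Wono152250 (859.6 ± 187 CPM) was 33400 times higher (interval 11900 to 168000). The methyltransferase Wono020700 was at least 4890-fold higher and the tryptophan aminotransferase-related gene Wono076000 at least 4480-fold. On the ovule side, AGAMOUS Wono428320 was 57800 times higher (interval 10100 to 2220000). The growth regulator GRF2 Wono093880 (contig_16572, bases 1684483 to 1687613, 5 exons; 291.8 ± 12.9 CPM) was at least 5750-fold lower in pollen, the sugar transporter SWEET Wono475980 (211.7 ± 69.9 CPM) at least 4170-fold, and the wall enzyme XTH Wono392140 (210.8 ± 51.1 CPM) at least 4160-fold. Lipoxygenase Wono068630, which oxidises fatty acids, had 83, 65 and 817.5 CPM in ovule libraries 1, 2 and 3 (at least 6350-fold lower in pollen; edgeR adjusted p = 0.00114), and myrcene synthase Wono107540, of monoterpene synthesis, had 5.29, 12.7 and 577 CPM (at least 3910-fold; edgeR adjusted p = 0.0126). Without ovule library 3 the bounds were 1460-fold for Wono068630 and 177-fold for Wono107540.

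**Figure D4:**
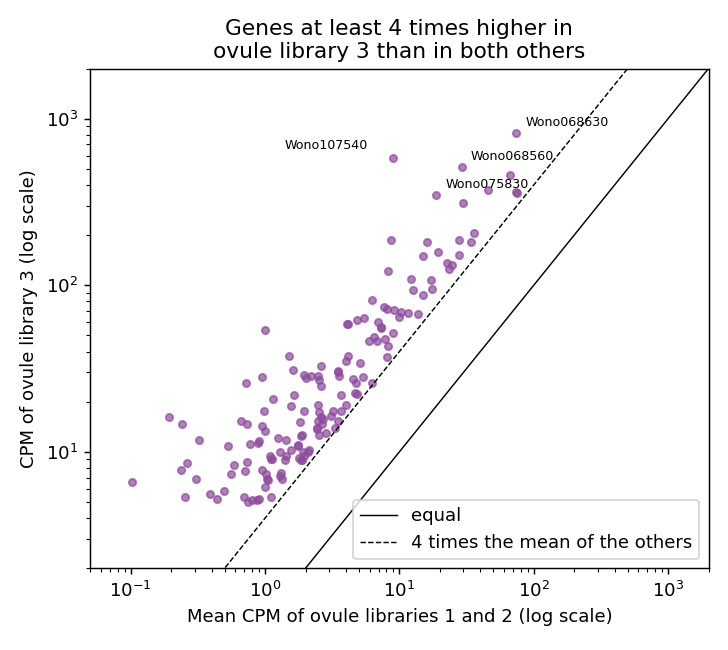
CPM in ovule library 3 against the mean of ovule libraries 1 and 2, for the 152 genes at least 4 times higher in library 3 than in both others; the axes are logarithmic, with lines at equal values and at 4 times. The myrcene synthase Wono107540 stood at 577 CPM, and the lipoxygenase Wono068630 at 817.5 CPM.

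Ribosomal protein, cell cycle, MADS-box, organ boundary, cuticle and photosystem lists fell in pollen against ovule. Of 129 ribosomal protein genes 66 were lower and 5 higher (median log2 change -1.01; camera adjusted p = 2.05e-06, and adjusted p = 0.646 with an estimated correlation), and of 26 cell cycle genes 21 were lower and 1 higher (median -4.72, or -4.46 with bounds; camera adjusted p = 0.00022, and adjusted p = 0.346 with an estimated correlation). Of 26 MADS-box genes 22 were lower and 2 higher (median -8.16, or -6.83 with bounds; camera adjusted p = 0.000167, and adjusted p = 0.246 with an estimated correlation), among them GGM13 Wono119760, 13100 times lower (interval 2290 to 504000), and MADS16-like Wono110200, at least 2120-fold lower. The GGM5 fragment Wono338670 had 0 counts in ovule and was at least 21.7-fold higher in pollen, at 0.537 CPM. Of 23 ovule and organ boundary regulators 19 were lower and 1 higher (median -5.74, or -3.74 with bounds; camera adjusted p = 0.0013, and adjusted p = 0.346 with an estimated correlation). Of 23 cuticle and wax genes 14 were lower and 0 higher (median -3.24, or -3.55 with bounds; camera adjusted p = 0.0106, and adjusted p = 0.246 with an estimated correlation). The photosystem genes were lower in 26 of 33 and higher in 5 (median -5, or -5.23 with bounds; camera adjusted p = 0.0106, and adjusted p = 0.646 with an estimated correlation), and with library totals the call ended (0.114, in a range of 0.0049 to 0.114 with the preset correlation).

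Of the seed storage, oil body and late embryogenesis list, pollen against ovule had 16 of 23 higher and 4 lower (median log2 change 7.99, or 6.29 with bounds; camera adjusted p = 0.000248, and adjusted p = 0.246 with an estimated correlation), with oleosin Wono328570 304 times higher. Actin genes had 16 higher and 10 lower of 46 (median 0.53, or 0.68 with bounds, but -0.36 with library totals; camera adjusted p = 0.0252, and adjusted p = 0.346 with an estimated correlation). The actin call ended with library totals (camera adjusted p = 0.118) and with the list as first matched (0.058), in a range of 0.0173 to 0.118 with the preset correlation; the actin-binding profilin Wono238970 had a log2 change of 7.76. Immune genes were lower in 110 of 177 and higher in 36 (median -4.21, or -3.55 with bounds; camera adjusted p = 0.0247, and adjusted p = 0.246 with an estimated correlation), and terpenoid genes lower in 19 of 29 and higher in 1 (median -5.64, or -4.27 with bounds; camera adjusted p = 0.0316, and adjusted p = 0.346 with an estimated correlation). With library totals the immune p was 0.619, in a range of 0.00991 to 0.619 with the preset correlation, and the terpenoid p 0.267, in a range of 0.0144 to 0.267 with the preset correlation. Ovule library 3 stood apart in the terpenoid list (sums of 176.1, 158.6 and 1272 CPM in ovule libraries 1, 2 and 3), and without it the terpenoid p was 0.0144. The chitinase-like gene Wono092750 was 3520 times higher in pollen and the resistance-type gene Wono395170 had a log2 change of -11.51.

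Other lists did not pass camera in pollen against ovule. Sporopollenin genes had 1 higher and 8 lower of 11 (median log2 change -5.79; adjusted p = 0.0582); the p was 0.0435 with RLE scaling, 0.0393 with a replicate block and 0.0252 without ovule library 2, in a range of 0.0252 to 0.274 with the preset correlation; it was 0.346 with an estimated correlation. Chlorophyll synthesis had 2 higher and 5 lower of 11 (0.476), and protochlorophyllide oxidoreductase Wono213000 (contig_24276, bases 35009720 to 35013244, 5 exons), which makes chlorophyllide in the light, stood at 1054 ± 126 CPM in pollen, 48 in ovule and 752.5 in leaf. Pectin enzymes had 14 higher and 26 lower of 44 (0.714), with pectinesterase Wono178950 40.2 times higher and Wono387360 893 times lower (interval 307 to 4340). DNA methylation and small RNA genes had 8 higher and 18 lower of 33 (0.392), and SGS3 Wono344850 was at least 1210-fold lower in pollen. Flavonoid genes had 13 higher and 21 lower of 40 (0.986), with chalcone synthase Wono365340 981 times higher. Sugar and starch genes had 19 higher and 24 lower of 68 (0.986), with alpha-amylase Wono387820 35 times higher; camera's direction was up with a median of -0.47, and likewise for phenylpropanoid (-0.59) and xylem (-0.22, or 0.07 with bounds). Phenylpropanoid had 15 higher and 25 lower of 62 (0.85; cinnamate hydroxylase Wono285000 -4.40), heat shock 8 and 25 of 54 (0.429; HSP21 Wono198410 5.98), pollen tube signalling 2 and 9 of 13 (0.139), Calvin cycle 1 and 5 of 10 (0.608), xylem 1 and 2 of 7 (0.986) and stomatal lineage 0 and 4 of 5 (0.173). Light signalling had 6 higher and 13 lower of 26 (0.476), or 14 lower adjusted over the list alone; all other counts of this comparison were the same adjusted over the list alone.

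Too few members of the remaining lists were tested. Of 5 tapetum regulators 2 were tested, with sums of 1.09 CPM in leaf, 11.3 in ovule and 1.90 in pollen. Of 5 meiosis genes 4 were tested (13.5, 31.4 and 35 CPM), and of 24 transposable element proteins 4 (95.1, 28.9 and 4.28 CPM). In all, camera called 33 of 69 pairs of list and comparison, and with an estimated correlation 0, where 13 had an unadjusted p under 0.05; limma's rotation test fry called 60.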

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

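The lists as first matched and the counts without ovule library 3 and pollen library 3 together were tested only after the data were seen. The total of called genes stayed within 1.5 times in each of the 3 comparisons under the alternatives run, but in pollen against ovule the genes called higher went from 5404 to 3430 with library totals. The totals ranged over the alternatives from 13847 to 18920 in pollen against leaf (15337 to 15733 with 1 library left out), from 12015 to 18259 in ovule against leaf (13697 to 14142) and from 12993 to 18380 in pollen against ovule (14476 to 14844). Without both libraries that stood apart the counts were 15520, 14140 and 14637. DESeq2 called 16423, 14510 and 15432 genes, which included 15044 (98.2%), 13202 (96.3%) and 13903 (95.9%) of edgeR's calls. The genes highest in pollen, 3711 with TMM, were 2460 with library totals and 2209 with a log2 change of at least 2 in both comparisons. The second is a stricter threshold. The first leaves out the TMM factors, 0.708 to 0.73 in pollen, 1.03 to 1.05 in leaf and 1.3 to 1.36 in ovule. Without them pollen levels are lower relative to both other tissues. Which scaling is closer to the true levels was not tested. With library totals the genes highest in ovule went from 4399 to 5990 and those highest in leaf from 5163 to 4929, so that their order turned. With 1 library left out, genes highest in leaf ranged from 5144 to 5384, in ovule from 4370 to 4558 and in pollen from 3688 to 3858, and those differing among the tissues from 22183 to 22489. Genes detected with 1 library left out ranged from 16828 to 16912 in leaf, from 17107 to 17230 in ovule and from 13450 to 13544 in pollen. The labels share replicate numbers between tissues, but libraries with the same number did not deviate together (r from -0.0682 to 0.0428 over 9 pairs; 5 of 18 best matches share the number), so the numbers were not taken as pairs. With a replicate block the counts were 15236, 13652 and 14347, and 35 lists were called. Of the gene list tests, 33 were called with a preset correlation, 32 to 35 with 1 library left out, 25 with library totals, 0 with an estimated correlation (camera) and 60 by fry, which does not compare a list with other genes. Under fry the direction reversed for lists that camera had not called: actin (0.00757) and flavonoids (0.000973) in ovule against leaf, and xylem (0.00356) and sugar transport (0.00289) in pollen against ovule; the cause was not tested. Of 287 calls of named genes none reversed; 286 to 287 held with 1 library left out, 279 with library totals, 284 with RLE factors, 286 with the block and 281 of 285 with DESeq2, which gave no adjusted p for Wono068630 and Wono107540 in pollen against ovule. These calls were chosen from the same libraries, many by large fold or small p. That they held was thus likely in advance and is no independent support. Depth limits the folds against tissues with 0 counts, which are lower bounds.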

Other observations

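The tests of leaf RNA, of pollen RNA and of reads running on between genes, the enrichment of terpenoid genes, the count of oxylipin enzymes and the split of the immune list were chosen only after the results were seen. The immune list was split by words in the descriptions, with no test between the parts. Of 124 genes whose description named resistance or NB-ARC, 115 were lower and 2 higher in pollen than in leaf, and 99 were lower and 5 higher than in ovule. In ovule against leaf 36 of them were higher and 60 lower. Their summed level was 2497 CPM in leaf, 2452 in ovule and 106.1 in pollen. The words do not show that each is a receptor of pathogen effectors. Of 16 BetVI proteins, small ligand-binding defence proteins, 8 were higher and 8 lower in pollen than in leaf, 11 higher and 2 lower than in ovule, and 3 higher and 12 lower in ovule than in leaf. Their sums were 83.8, 19.24 and 45630 CPM, and Wono297510 alone made up 45530 of the last. The other 37 chitinases, thaumatins and defence proteins had 12 higher and 17 lower in pollen than in leaf, 20 higher and 9 lower than in ovule, and 6 higher and 22 lower in ovule than in leaf, with sums of 370.5, 478.8 and 1368 CPM.

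The further genes named here were chosen after their values were seen, and no test covers them as a group. The list of ovule and organ boundary regulators did not pass in ovule against leaf (camera adjusted p = 0.562), and its sum was 913.9 CPM in ovule and 2307 in leaf. Among its members, the WUSCHEL-like genes Wono378950 (43.1 CPM) and Wono404820 (8.85 CPM) had 0 counts in leaf and pollen, and the LEAFY homologs Wono251580 and Wono332270 reached 6.55 and 1.1 CPM in ovule. The replication licensing genes MCM2 Wono459720 (597.2 CPM), MCM3 Wono089040 (339.7 CPM), MCM5 Wono106940 (323.6 CPM) and MCM7 Wono404430 (333 CPM) stood at these levels in ovule. In pollen, the oleosins Wono253650 (1326 CPM) and Wono253670 (240.6 CPM) and the late embryogenesis gene Wono173010 (472.2 CPM) were further members of the seed storage, oil body and late embryogenesis list. The retroelement gene Wono448570 stood at 65.1 CPM in leaf, 0.0153 in ovule and 0 in pollen.

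Ovule library 3 had 152 genes of at least 5 CPM that were at least 4 times higher than in both other ovule libraries; the other libraries had 0 to 26 such genes, the highest number in pollen library 3. They held 4 of 29 terpenoid genes (one-sided Fisher's exact p = 3.97e-05, adjusted p = 0.000914 over 23 lists), which lay on 3 contigs, so that the test counts neighbouring copies as independent. They also held 6 of 25 oxylipin enzymes, a group made after the set was seen, so that a test of it would be void. All 6 lay on 1 contig, among them allene oxide synthase Wono068560, chosen after its values were seen (33, 25.4 and 509.4 CPM in libraries 1, 2 and 3). RNA from leaf or pollen is argued against as the source, since the excess was larger than the whole leaf level in 85.5% of the genes and larger than the whole pollen level in 78.9%. The median log2 ratio of the 54 heat shock genes was -0.17 (95% interval -0.25 to -0.03, with genes taken as independent), and 0 of them were in the set. These values argue against a broad heat shock response at harvest. A median would not show smaller changes of a few members. No other biological explanation was tested, since the labels give no difference between the ovule samples, and the source of the excess stays open.

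Fewer genes were detected in pollen than in leaf. With all libraries thinned to 25602114 counts, pollen had 13317 genes, 79.6% of the 16727 in leaf (SD 0.056 over thinnings). Thinning removed few counts and detection is set in CPM, so this could hardly have come out otherwise. The totals themselves were alike, 25602114 to 28517315 in pollen and 26384085 to 28325689 in leaf, which argues against depth as the cause. With the 1000 most abundant genes of each tissue left out, pollen had 81.3% (13177 against 16200; SD 0.076), which argues against a few abundant genes taking the counts. A smaller set of expressed genes in pollen, a tissue difference that the design names, may remain as an explanation and is a hypothesis found on the same data.

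Neighbours are here tested genes that follow each other on a contig without overlap. Untested genes between them were passed over and no limit of distance was set, so a pair need not be adjacent in the annotation. Neighbouring genes were highest in the same tissue in 3495 of 19994 pairs, 1.33 times as often as in shuffled orders (95% range 1.29 to 1.36). Where the descriptions shared a word the ratio was 2.52 (2.24 to 2.84), and where they shared none it was 0.893 (0.828 to 0.962). Copies of a family side by side are consistent with this, but only 5859 pairs had both genes described and they held 28.4% of the excess; for the other 14135 pairs (1.32 times, 1.28 to 1.37) the descriptions decide nothing. The shuffles moved calls among all tested genes of a contig, but pairs split by words need both genes described. Genes with a description were less often highest in leaf (46.6% of the genes highest there had one, against 50.8% of those tested). Ratios of described pairs can thus lie below 1 without any link between neighbours. Reads running on into the next gene also stay open. Among pairs sharing no word, those not pointing apart had an odds ratio of 1.41 (95% interval 1.11 to 1.81, with pairs taken as independent) against those pointing apart, which cannot run on. Their ratios to shuffled orders, 0.955 (0.88 to 1.04) and 0.707 (0.612 to 0.83), cannot be read against 1. Over all descriptions, pairs pointing apart still had a ratio of 1.15 (1.08 to 1.24), which running on leaves unexplained.

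Other splits of the libraries were counted. For each pair of tissues the 6 libraries have 10 splits, too few for a share under 0.05; the real split called 14520 genes in pollen against leaf, 13373 in ovule against leaf and 13676 in pollen against ovule, with only these tissues in the fit, and the highest of the others called 0. Of 100 regroupings of the 9 libraries (280 are possible), 1, the real one, gave as many genes differing among the tissues (22021, highest other 6238). Likewise 1 each gave as many highest in leaf (5163), ovule (4399) and pollen (3711, highest other 3418). Every other regrouping mixed tissues within groups, which widens the spread there. The shares show only that grouping by tissue called more genes than the mixed groups did, and they cannot exclude chance. For the gene list tests, 9 of 100 regroupings called as many lists (33 in the real one, highest other 36). The mixed groups still carry differences between tissues, so this share cannot decide whether the list calls arose by chance, which is not excluded.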
